A study of Mus musculus with 6 samples.

How the data were processed

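Total RNA of mouse liver was extracted with Trizol, and the labels' protocols name an Illumina TruSeq DNA kit for library construction; whether the libraries keep strand is not given in the sources used here. Per the labels, 3 offspring of saline-treated fathers and 3 offspring of nicotine-treated fathers were sequenced, and groups were taken from these labels. The labels do not say from how many fathers or litters the animals came, so p-values measure the spread between these 6 animals.

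The authors deposited 1 table per library with RPKM values for 54532 Ensembl genes and a column of gene lengths in bases. CASAVA, TopHat and the build mm8 are listed in the submitters' processing notes, without versions; the counting tool, the annotation and the treatment of reads with several matches are not given in the sources used here. Of the gene identifiers, 99.93% matched GENCODE M21, an annotation of the later build GRCm38, which supplied symbols and coordinates. A gene with no read holds a placeholder of at most 1.6e-08 RPKM per the file values, which was set to 0. The deposited RPKM values were made with the summed exon length of all annotated transcripts of a gene: 98.9% of the genes without a read matched that length within a relative tolerance of 1e-06. How reads were counted over transcripts is not given, so levels may not compare between genes with different numbers of transcripts, while 1 length per gene leaves fold changes between libraries as they are. The deposited lengths (another unit, bases) matched the row's own gene in 96 rows, 0.18%, and were not used.

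The placeholders had fixed ratios between libraries and gave the totals of reads behind the RPKM values: 61837267, 66928579 and 64223476 in paternal saline replicates 1 to 3 and 62102561, 62072258 and 70089315 in paternal nicotine replicates 1 to 3. With these totals the values of all 25531 genes with a read corresponded to whole reads within 0.01; for 1021 of them the length had to be searched. Read numbers of 4 were more frequent than those of 3, 4135 against 1576 values, so a read may not be an independent fragment. Floors of 3 reads per library cover counting error only.

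For the main test, limma 3.58.1 (R 4.3.3; lmFit and eBayes with trend and robust) was run on log2(RPKM + 1) of the 8773 genes with a mean of at least 1 RPKM, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design had been written for counts or for a normalized unit, and the files hold the latter. The design, the gene lists, the rule for named genes and all but the added alternatives were fixed before the data were examined. Gene lists were tested with camera at a preset correlation of 0.01, for 27 pathway lists and 15 cell type and RNA quality lists with at least 5 tested members, adjusted within each family. Alternatives were an estimated correlation and fry. The estimated correlation comes from the same 6 libraries, and the power of that version was not tested in the simulation. A list that did not pass in it may therefore still differ. The row with the highest mean stood for a repeated symbol. Members that were not found or had a mean under 1 RPKM were not tested, so list counts cover tested members only. The rule for named genes takes the 10 largest rises and 10 largest falls past the threshold with non-overlapping groups and a gene name, 14 genes of fibrosis and Wnt signalling, and up to 4 members of lowest p per list described. Atf4, Fgb, Saa1 and the members of summed paralog families lie outside it and were chosen after their values were seen. Some genes that the rule takes are not reported here.

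The fit was tested on simulated data with the means and spread of the real genes. Of 50 genes changed 1.5-fold 8 were recovered, of 50 changed 2-fold 21, of 50 changed 4-fold 37 and of 50 changed 8-fold 44, with 5 false calls among 115; without any change there were 0 calls in 8773 genes.

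Alternatives were rescaling by the median ratio, quantile normalization, limma without trend and robust, no filter and a stricter filter, pseudocounts of 0.1 and 0.01, rows of a symbol summed, a replicate block, other thresholds and leaving out each library. Added after seeing the data were limma voom on the reads behind the RPKM values and leaving out genes whose values jump within a group. Overlapping genes share at least 50 exonic bases (bedtools 2.31.1), on either strand, and near-identical copies align over at least 200 bases at 95% identity or more (blastn 2.17.0). A further 8 lists had fewer than 5 tested members and were not tested. Figures were drawn with matplotlib 3.10.9.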

Results

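Liver RNA was sequenced from 6 adult male C57BL/6J mice, each 8 weeks old, in 2 groups of 3. The fathers of the paternal saline group had received saline, and the fathers of the paternal nicotine group had received nicotine. The offspring themselves carry no treatment in the labels. The series is about paternal nicotine and liver fibrosis in the offspring, so the single comparison asked which liver transcripts differed between the offspring of nicotine-treated and saline-treated fathers. The values are RPKM, that is reads divided by gene length and library size, for 54532 genes per library. The totals behind these values ranged from 61837267 reads in paternal saline replicate 1 to 70089315 reads in paternal nicotine replicate 3, and the number of genes at 1 RPKM or more ranged from 8383 to 8994. Genes with a mean of at least 1 RPKM over the 6 libraries were tested, 8773 in all. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes, and coordinates are those of GENCODE M21 on GRCm38.

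The libraries of the 2 groups lay apart on the first principal component, which held 42.5% of the variance. The Pearson correlation of log values across genes, which are not independent replicates, averaged 0.956 within groups and 0.931 between groups. Paternal nicotine replicate 2 and replicate 3 had the lowest correlation within a group, 0.939. As a check for duplicated libraries, the chi-square per degree of freedom of the reads was computed for each pair of libraries, and it was at least 178.5.

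**Figure D1:**
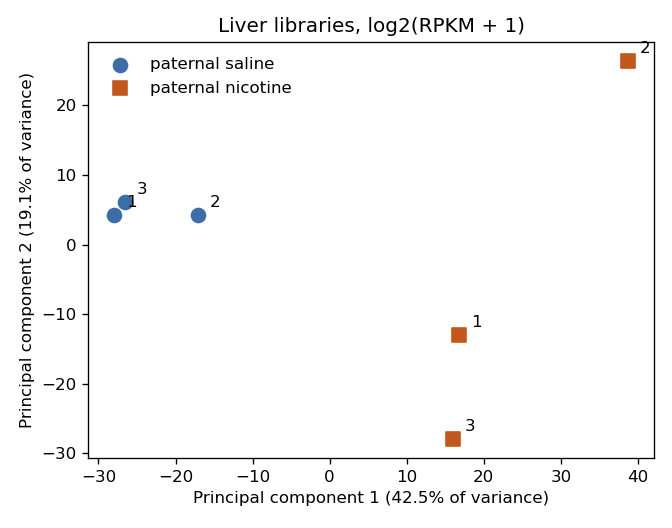
Principal component 1 (horizontal, 42.5% of variance) against principal component 2 (vertical, 19.1% of variance) of the 8773 tested genes, log2(RPKM + 1); circles are paternal saline and squares paternal nicotine libraries, numbered by replicate. The 3 paternal saline libraries lie between -27.97 and -17.09 on component 1 and the 3 paternal nicotine libraries between 16.05 and 38.75.

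In livers of the paternal nicotine group, 19 of 30 tested genes of acute phase proteins, which the liver secretes during inflammation, rose and 2 fell. Of 29 tested genes of the unfolded protein and integrated stress response 18 rose, and of 25 tested bile acid genes 12 fell. These 3 lists passed in camera with a preset correlation, and each was at adjusted p = 0.169 with an estimated correlation. Lcn2, which encodes an iron-sequestering acute phase protein, rose from 1.95 ± 1.65 to 196 ± 41.2 RPKM (SD, n = 3 per group), and Hp, which encodes haptoglobin, rose from 1474 ± 197 to 6899 ± 394 RPKM. Among the bile acid genes Slco1b2, a carrier that takes up bile acids and drugs, fell from 98.7 ± 18.0 to 4.10 ± 3.59 RPKM. Among fibrosis genes, Col1a1 and Acta2 had means between 1.40 and 1.89 RPKM in both groups, and Timp1, an inhibitor of matrix-degrading enzymes, rose from 0.0987 ± 0.110 to 7.81 ± 2.25 RPKM. In limma with Benjamini-Hochberg adjustment, 814 genes passed an adjusted p of 0.05, of which 341 were higher and 473 lower in paternal nicotine. All 814 had groups that did not overlap. Of all tested genes, 33.6% did not overlap, against 10% expected by chance.

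Of the 10 largest rises, 7 were of genes in the acute phase list, Lcn2 among them. Saa2 (ENSMUSG00000057465, chromosome 7, 46751790 to 46754313) rose by 7.26 on the log2 scale (SE 0.76, limma adjusted p = 0.00691), from 2.97 ± 4.27 to 414 ± 95.5 RPKM. Saa2 has a near-identical copy, Saa1, whose value in paternal nicotine replicate 2 was 4187 RPKM against 327 and 133 in the other 2 libraries of that group, so the division of reads between Saa1 and Saa2 is uncertain. Saa3 reached 76.6 ± 40.9 RPKM from 2.35 ± 1.94, Apcs reached 2203 ± 123 from 196 ± 118, and Serpina3n reached 1162 ± 335 from 118 ± 45.3. Cxcl1, which encodes a neutrophil-attracting chemokine, rose from 1.96 ± 1.70 to 68.5 ± 14.2 RPKM. The metallothionein gene Mt1 rose from 52.4 ± 37.4 to 931 ± 417 RPKM, and the fatty acid-binding protein gene Fabp5 from 3.93 ± 1.60 to 48.4 ± 10.4 RPKM.

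Orm2 and Orm1, neighbouring genes for orosomucoid on chromosome 4, moved in opposite directions. Orm2 (63362449 to 63365878) rose from 21.7 ± 6.50 to 813 ± 69.2 RPKM, with a log2 fold change of 5.21 (SE 0.23, limma adjusted p = 0.0011). Orm1 (63344560 to 63348163) fell from 1005 ± 150.3 to 129 ± 3.10 RPKM, with a log2 fold change of -2.94 (SE 0.12, limma adjusted p = 0.000866). Their sum was 1027 ± 155 RPKM in paternal saline and 943 ± 71.2 RPKM in paternal nicotine, and neither has a near-identical copy at 95% identity over 200 bases. That cutoff does not exclude reads shared between paralogs of lower identity. The treatment of reads with several matches is not given, so the division of reads between Orm1 and Orm2 is uncertain.

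Of the 30 tested genes of the acute phase list, 19 rose, 2 fell and 9 did not pass, and 26 passed when adjusted over the list alone, 24 higher and 2 lower. The 2 that fell were Orm1 and Hamp2, while the sum of Hamp and Hamp2 was higher in paternal nicotine. The list moved up as a whole (camera adjusted p = 5.25e-15, adjusted p = 0.169 with an estimated correlation). The fibrinogen gene Fgb rose from 1357 ± 379 to 4523 ± 813 RPKM. The summed level of neutrophil markers was 229 to 271 RPKM in the same livers against 7.27 to 12.1 RPKM. Without Lcn2, which is in both lists, it was 28.1 to 89.5 RPKM against 6.36 to 8.24 RPKM. Of 29 tested genes of the unfolded protein and integrated stress response, 18 rose, 0 fell and 11 did not pass, and 22 passed when adjusted over the list alone (camera adjusted p = 5.27e-16, adjusted p = 0.169 with an estimated correlation). Creld2 rose from 34.0 ± 8.45 to 168 ± 7.56 RPKM, Hyou1 from 4.49 ± 0.820 to 14.5 ± 0.447 RPKM, Hspa5 from 33.0 ± 4.08 to 86.3 ± 6.84 RPKM and Hsp90b1 from 53.6 ± 2.07 to 113 ± 8.93 RPKM. These are a secreted stress protein and chaperones of the endoplasmic reticulum. The transcription factor gene Atf4 was at 32.1 RPKM in paternal saline and 32.3 RPKM in paternal nicotine.

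Inflammatory and immediate early genes moved up with fewer single calls. Of 21 tested inflammatory cytokine, chemokine and NF-kappaB genes 4 rose, 0 fell and 17 did not pass, and 13 passed when adjusted over the list alone, 12 higher and 1 lower (camera adjusted p = 6.41e-07, adjusted p = 0.44 with an estimated correlation and 0.0528 in fry). The 4 that rose were Cxcl1, the adhesion molecule gene Icam1, at 4.74 ± 1.02 against 16.4 ± 2.66 RPKM, the adaptor gene Myd88, at 6.76 ± 0.850 against 11.7 ± 0.0716 RPKM, and the chemokine gene Ccl6, at 8.58 ± 1.27 against 24.5 ± 8.13 RPKM. Markers of macrophages, dendritic cells, and T and NK cells were highest in paternal nicotine replicate 3, where Kupffer cell and macrophage genes summed to 1506 RPKM against 466 to 932 RPKM in the other 5 libraries. Dendritic cell genes summed to 810.02 against 215 to 395 RPKM, and T and NK cell genes to 34.7 against 4.403 to 10.6 RPKM. Within paternal saline, replicate 3 was also highest for macrophage genes, at 932 RPKM, and dendritic cell genes, at 395 RPKM. For T and NK cell genes it was not. Of 24 immediate early and heat shock genes 6 rose and 18 did not pass, and 9 passed when adjusted over the list alone (camera adjusted p = 0.000327, adjusted p = 0.48 with an estimated correlation and 0.0942 in fry). Junb was at 22.1 ± 5.57 in paternal saline and 94.1 ± 9.22 RPKM in paternal nicotine. The fasting and glucocorticoid list had 2 of 22 members up and 20 that did not pass, with 4 when adjusted over the list alone (camera adjusted p = 0.00204, adjusted p = 0.475 with an estimated correlation and 0.077 in fry). The 2 were Lcn2 and Mt1, both also in the acute phase list. None of the 24 cholesterol synthesis genes passed, over all genes or adjusted over the list alone, while 20 had a positive fold change (camera adjusted p = 0.00314, adjusted p = 0.618 with an estimated correlation, 0.423 in fry and 0.0934 without paternal saline replicate 3).

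Of 25 tested bile acid synthesis and transport genes 12 fell, 0 rose and 13 did not pass, and 21 passed when adjusted over the list alone, of which 20 were lower (camera adjusted p = 1.03e-09, adjusted p = 0.169 with an estimated correlation). Slco1b2 (ENSMUSG00000030236, chromosome 6, 141629518 to 141686646) fell by 4.49 on the log2 scale (SE 0.47, limma adjusted p = 0.00691). Slco1a1 fell from 19.1 ± 3.28 to 2.69 ± 0.134 RPKM, Slco1a4 from 5.86 ± 0.345 to 0.668 ± 0.221 RPKM, and Akr1d1, which encodes a bile acid-forming reductase, from 40.0 ± 3.44 to 8.29 ± 1.76 RPKM. Of 26 targets of the receptors CAR, PXR and AhR 8 fell, 1 rose and 17 did not pass, with 11 adjusted over the list alone, 10 lower and 1 higher (camera adjusted p = 0.000238, adjusted p = 0.169 with an estimated correlation). The sulfotransferase gene Sult1d1 fell from 45.3 ± 13.7 to 9.33 ± 0.193 RPKM and Cyp2c29 from 165 ± 20.0 to 64.9 ± 7.47 RPKM. Of 11 genes of nicotine and cotinine metabolism 4 fell and 7 did not pass, with 6 adjusted over the list alone (camera adjusted p = 0.00124, adjusted p = 0.169 with an estimated correlation): Ugt2b36, at 105 ± 15.5 against 38.8 ± 0.699 RPKM, Ugt2b34, Cyp2a12 and Fmo1.

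Oxidative phosphorylation genes encoded in the nucleus fell in 13 of 61 cases, 48 did not pass, and 38 passed when adjusted over the list alone, all lower (camera adjusted p = 9.89e-14, adjusted p = 0.331 with an estimated correlation). Sdhd fell from 240 ± 2.57 to 148 ± 7.29 RPKM and Ndufa6 from 64.4 ± 4.0015 to 36.8 ± 2.78 RPKM. Transcripts encoded in mitochondria, which also follow RNA quality, moved with the group: the 13 genes had a median log2 fold change of -0.30, 1 of them passed (mt-Co1, lower), and 8 passed when adjusted over the list alone (camera adjusted p = 0.000163, adjusted p = 0.797 with an estimated correlation). The fold change of mt-Co1 was 0.19 with quantile normalization. Mitochondrial genes held 18.6% to 19.2% of the RPKM total in paternal saline and at most 17.2% in paternal nicotine. Of 25 periportal hepatocyte genes 10 fell, 2 rose and 13 did not pass, with 17 adjusted over the list alone, 14 lower and 3 higher (camera adjusted p = 0.00124, adjusted p = 0.169 with an estimated correlation), among them the glutaminase gene Gls2, from 31.4 ± 0.485 to 13.9 ± 1.16 RPKM. Of 23 pericentral genes 3 fell and 20 did not pass, with 6 adjusted over the list alone (camera adjusted p = 0.0221, adjusted p = 0.44 with an estimated correlation and 0.085 with quantile normalization). Of 26 male-biased genes 7 fell and 19 did not pass, with 15 adjusted over the list alone, 13 lower and 2 higher (camera adjusted p = 0.00124, adjusted p = 0.44 with an estimated correlation), among them Cyp2f2, from 257 ± 36.6 to 105 ± 21.3 RPKM.

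The remaining large falls were of Inmt, an amine methyltransferase gene, from 413 ± 61.4 to 66.9 ± 7.68 RPKM, and the carboxylesterase gene Ces1d, from 182 ± 25.9 to 34.1 ± 2.22 RPKM. Car3, a carbonic anhydrase gene, fell from 510.05 ± 232 to 60.4 ± 12.2 RPKM, Akr1c6 from 324 ± 65.1 to 60.98 ± 42.8 RPKM, and the hepcidin paralog Hamp2 from 60.7 ± 5.77 to 9.70 ± 2.64 RPKM. The sum of Hamp and Hamp2 went the other way, at 1307 ± 346 RPKM in paternal saline and 3447 ± 1196 RPKM in paternal nicotine. S100a13 was at 34.3 to 37.3 RPKM in paternal saline and at 0, 5.52 and 0 RPKM in paternal nicotine. Mup17 was at 247, 42.5 and 3446 RPKM in paternal saline and at 0 in all 3 paternal nicotine libraries. Against a floor of 3 reads per library it was at least 815-fold lower than in the lowest paternal saline library. Mup17 has 15 near-identical copies, and the sum of all 22 Mup genes was 15719 ± 4165 against 9249 ± 1187 RPKM, so its own value is uncertain. Of the 20 genes with the largest changes, 14 passed in every alternative that tested them, while Saa3, Mt1, Mup17, S100a13, Car3 and Akr1c6 did not.

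**Figure D2:**
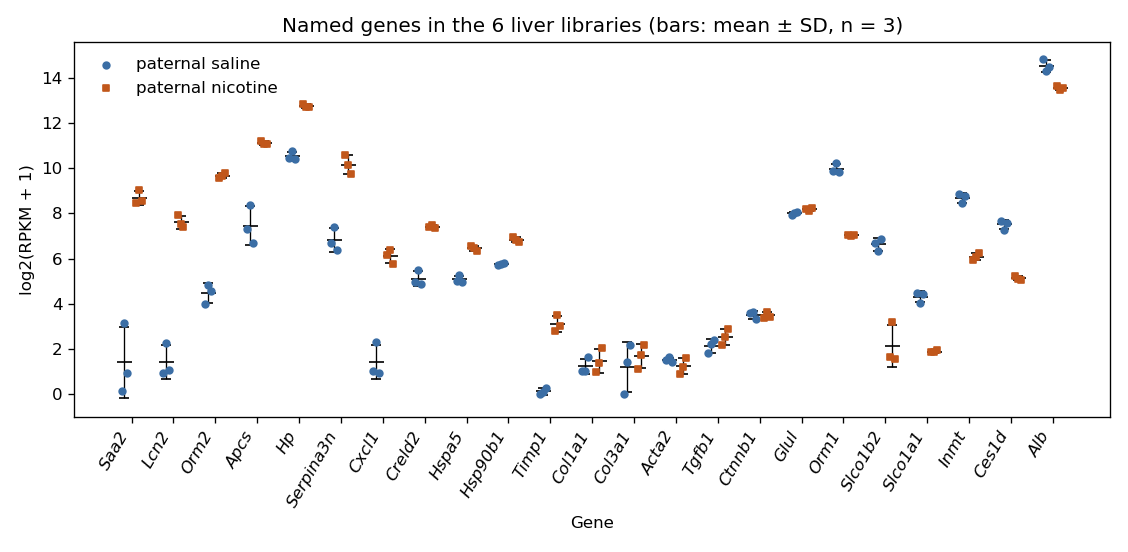
Level of 23 named genes as log2(RPKM + 1) in each library; circles are paternal saline and squares paternal nicotine, with the mean and SD of 3 libraries as bars. Lcn2 rose from 1.95 to 196 RPKM, Hp from 1474 to 6899 RPKM and Timp1 from 0.0987 to 7.81 RPKM, while Col1a1 was at 1.41 and 1.89 RPKM.

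In all, 14 genes had been fixed in advance, of which 11 had a mean of at least 1 RPKM and were tested. For the fibrosis question there were 9, of which 7 were tested. Timp1 (ENSMUSG00000001131, chromosome X, from 20870166) was the 1 gene of the 11 that passed, over all genes and adjusted over the list alone, with a log2 fold change of 2.98 (SE 0.19, limma adjusted p = 0.00233). Col1a1 was at 1.41 ± 0.597 against 1.89 ± 1.11 RPKM (log2 fold change 0.23, SE 0.31). Acta2, the smooth muscle actin of myofibroblasts, was at 1.88 ± 0.200 against 1.40 ± 0.604 RPKM (log2 fold change -0.29, SE 0.19). Col3a1 was at 0.00383, 1.65 and 3.51 RPKM in the paternal saline libraries and at 1.19, 2.31 and 3.54 RPKM in the paternal nicotine libraries. The growth factor gene Tgfb1 was at 3.48 ± 0.884 against 4.88 ± 1.37 RPKM, Ccn2 at 1.97 ± 1.17 against 2.70 ± 1.27 RPKM and Des at 1.86 ± 0.252 against 2.08 ± 0.404 RPKM. Col1a2 and Pdgfrb were below the tested range, at 0.707 and 0.167 RPKM in paternal saline and 0.415 and 0.298 RPKM in paternal nicotine. Without a filter on low values their log2 fold changes were -0.29 (SE 0.22) and 0.14 (SE 0.18), and neither passed.

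Of 18 tested genes of matrix proteins and matrix turnover, of 34 listed, 4 rose, 1 fell and 13 did not pass. Adjusted over the list alone 6 passed, 5 higher and 1 lower (camera adjusted p = 0.00518, adjusted p = 0.44 with an estimated correlation). Besides Timp1, Spp1 rose from 5.597 ± 0.915 to 9.54 ± 1.20 RPKM, and the proteoglycan gene Fmod fell from 1.78 ± 0.395 to 0.807 ± 0.165 RPKM. Timp1 is known also to respond to inflammation. Of 19 listed collagen genes 8 were tested. Col14a1 alone passed, over all genes and adjusted over the list alone, from 0.837 ± 0.469 to 3.03 ± 0.579 RPKM. Of the 8 genes 7 had a positive fold change (median log2 fold change 0.24), and the list leaned up without passing (camera adjusted p = 0.103). The collagen list passed upward in camera without paternal saline replicate 1 (adjusted p = 0.0489) and without paternal saline replicate 3 (adjusted p = 0.00154). It also passed upward without paternal nicotine replicate 1 (adjusted p = 0.0399). It was at 0.292 without paternal nicotine replicate 3, the library with the highest macrophage markers. None of 24 tested TGF-beta genes, of 34 listed, passed over all genes or adjusted over the list alone. Of the 24 genes 17 had a positive fold change, and the list leaned up (camera adjusted p = 0.0778, and 0.0434 among genes with a mean of at least 5 RPKM). Of 11 tested markers of activated stellate cells, of 18 listed, 2 rose, 1 fell and 8 did not pass. Adjusted over the list alone 4 passed, 2 higher and 2 lower (camera adjusted p = 0.291). In fry's mixed test, which counts changes in either direction, these markers were at adjusted p = 0.000318. The collagen and TGF-beta lists were each at 0.132 in that test. Timp1 and Spp1 rose, and the myosin light chain gene Myl9 fell from 1.58 ± 0.0478 to 0.737 ± 0.183 RPKM.

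Wnt signalling was the other pathway fixed in advance. Ctnnb1, which encodes beta-catenin, was at 10.5 ± 1.28 against 10.3 ± 1.14 RPKM (log2 fold change -0.02, SE 0.12), Axin2 at 1.31 ± 0.227 against 1.57 ± 0.332 RPKM, Glul at 255 ± 13.8 against 289.9 ± 12.9 RPKM and Ccnd1 at 2.31 ± 0.737 against 2.74 ± 1.48 RPKM. Lgr5 was below the tested range, at 0.313 and 0.481 RPKM, and did not pass without a filter on low values (log2 fold change 0.18, SE 0.08). Of 60 listed Wnt ligands, receptors and regulators 22 were tested. None of the 22 passed, over all genes or adjusted over the list alone (camera adjusted p = 0.744, and 0.0017 in fry's mixed test, which counts changes in either direction). Of 18 tested Wnt target genes, of 22 listed, 1 rose, 1 fell and 16 did not pass. Adjusted over the list alone 3 passed, 2 lower and 1 higher (camera adjusted p = 0.744, and 6.66e-05 in fry's mixed test). Neither Wnt list thus moved in 1 direction. The mixed test does not say which members differ or which way, and no single ligand, receptor or regulator passed. Lists outside Wnt signalling were also low in that test. NRF2 targets were at adjusted p = 0.000276 in fry's mixed test, and DNA methylation and chromatin enzymes at 0.00094.

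**Figure D3:**
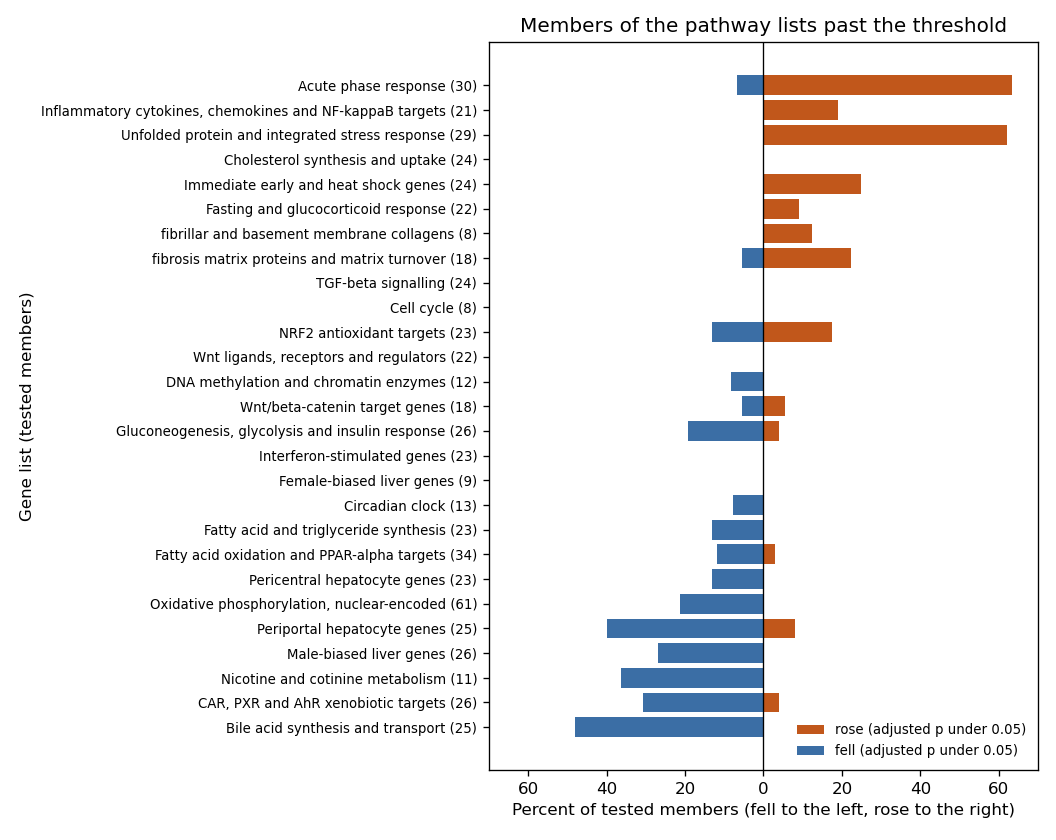
Percent of the tested members of each of 27 pathway lists that rose (to the right) or fell (to the left) in paternal nicotine at an adjusted p under 0.05 in limma; the number of tested members is in parentheses. Of 30 acute phase genes 19 rose and 2 fell, of 29 unfolded protein and integrated stress response genes 18 rose, and of 25 bile acid genes 12 fell.

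The other pathway lists did not pass in the main test. Of 23 fatty acid and triglyceride synthesis genes 3 fell, with 6 adjusted over the list alone (camera adjusted p = 0.0502). The list passed with median-ratio scaling (adjusted p = 0.0387), without a filter on low values (0.000502), without paternal saline replicate 3 (0.0019), without paternal nicotine replicate 1 (0.0246) and without genes whose values jump within a group (0.03), and was at the threshold with voom (0.05). Gluconeogenesis, glycolysis and insulin response had 5 of 26 genes lower and 1 higher, with 6 adjusted over the list alone, 5 lower and 1 higher (camera adjusted p = 0.078). That list passed without a filter on low values (adjusted p = 0.0103), without paternal saline replicate 1 (0.0275) and without paternal nicotine replicate 1 (0.0399), and in fry (0.0301). The glucose transporter gene Slc2a2 fell from 24.4 ± 2.04 to 4.09 ± 0.907 RPKM and the glycogen phosphorylase gene Pygl from 30.0 ± 1.69 to 10.4 ± 0.334 RPKM. Fatty acid oxidation had 4 of 34 genes lower and 1 higher, with 8 adjusted over the list alone, 6 lower and 2 higher (camera adjusted p = 0.29, and 0.0181 without paternal saline replicate 2). Among NRF2 targets 4 of 23 rose and 3 fell, with 10 adjusted over the list alone, 5 higher and 5 lower (camera adjusted p = 0.36). Hmox1 rose from 12.05 ± 2.99 to 47.6 ± 3.12 RPKM. A single member passed in the list of DNA methylation and chromatin enzymes (Sirt3, lower, camera adjusted p = 0.3) and in that of the circadian clock (camera adjusted p = 0.478), each with 1 adjusted over the list alone. None passed among 8 cell cycle genes (camera adjusted p = 0.472, and 0.0405 without a filter on low values), 23 interferon-stimulated genes (camera adjusted p = 0.679, and 0.0292 without paternal nicotine replicate 3) and 9 female-biased genes (camera adjusted p = 0.744), over all genes or adjusted over the list alone.

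Markers of other cell types were measured beside these groups, and 3 of 15 such lists passed, where other splits of the same libraries gave up to 10. Of 5 tested neutrophil genes, of 15 listed, 3 rose and 2 did not pass, with 4 adjusted over the list alone (camera adjusted p = 0.000163, adjusted p = 0.502 with an estimated correlation). S100a8 rose from 2.49 ± 0.668 to 30.5 ± 10.5 RPKM, and Lcn2 is in both this and the acute phase list. Pancreatic acinar genes were high in a single library: the 19 listed genes summed to 4801 RPKM in paternal nicotine replicate 2 and to between 3.09 and 5.34 RPKM in the other 5 libraries. Ctrb1, for chymotrypsinogen, was at 1621 RPKM there and at 0 in the other 5 libraries. None of 16 tested acinar genes passed, over all genes or adjusted over the list alone, although the list did (camera adjusted p = 0.0326, adjusted p = 0.88 with an estimated correlation, 0.637 in fry, 0.0901 with median-ratio scaling, 0.144 without paternal saline replicate 2 and 0.0885 without replicate 3). Of 15 hepatocyte markers 2 fell, 1 rose and 12 did not pass, with 7 adjusted over the list alone, 6 lower and 1 higher (camera adjusted p = 0.331, and 0.0179 in fry). The albumin gene Alb fell from 23798 ± 4438 to 11791 ± 694 RPKM. The 14 Kupffer cell and macrophage genes had no member past the threshold, over all genes or adjusted over the list alone (camera adjusted p = 0.18). That list passed without paternal nicotine replicate 1 (adjusted p = 0.000417) and without paternal saline replicate 3 (0.0235). The 10 quiescent stellate cell genes (camera adjusted p = 0.274, and 0.0196 without a filter on low values), 58 cytosolic ribosomal protein genes (camera adjusted p = 0.291, and 0.0045 with quantile normalization), 5 dendritic cell genes (camera adjusted p = 0.622), 5 intestine and stomach genes (camera adjusted p = 0.752) and 6 blood genes (camera adjusted p = 0.752) had none either, over all genes or adjusted over the list alone. The 18 sinusoidal endothelial genes likewise had none (camera adjusted p = 0.622), with a median log2 fold change of -0.03 and a mean of 0.05. Among 7 cholangiocyte markers Sox9 and Spp1 rose (camera adjusted p = 0.168), among 5 portal fibroblast and mesothelial markers Gas6 rose (camera adjusted p = 0.221), and among 7 histone and other RNAs without a poly(A) tail Hist1h1c rose (camera adjusted p = 0.168, and 0.0423 without paternal nicotine replicate 1), the same members as adjusted over the list alone.

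Of the 27 pathway lists 14 passed in camera with a preset correlation, 7 higher and 7 lower, and none passed with an estimated correlation, while other splits of the same libraries gave up to 14. Leaving out single libraries lowered the count of genes to 257 without paternal saline replicate 1, 365 without replicate 3, 273 without paternal nicotine replicate 1 and 185 without replicate 2, where 91 were higher and 94 lower.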

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

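The tests chosen after the result was seen are limma voom on the recovered reads, leaving out genes whose values jump within a group, and the choice of the collagen, fibrosis matrix, TGF-beta, Wnt and activated stellate cell lists as those that bear on the question. With 3 libraries per group, leaving out a library moved the count of genes more than scaling did. Leaving out a library also makes a group smaller and so lowers power, which was not separated from the part of that library. In the simulation 42% of genes changed 2-fold were recovered, so a gene that did not pass may still differ. The simulation had 115 calls against 814 here, so the share recovered may differ in the real data. Without single libraries the count of 814 genes ranged from 185 (paternal nicotine replicate 2, where 179 of the 185 were among the 814) to 658, the 341 higher from 91 to 301, and the 473 lower from 94 to 402.

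Without a filter on low values 367 genes passed (184 higher and 183 lower), with more genes tested. At an adjusted p of 0.1 in limma 1411 passed (587 and 824), at 0.05 with an absolute log2 fold change of at least 1 243 (123 and 120), and at an unadjusted p of 0.05 with that fold change 338 (172 and 166). Median-ratio scaling gave 838 genes, quantile normalization 817, limma without trend and robust 805, a mean of at least 5 RPKM 765, pseudocounts of 0.1 and 0.01 834 and 828, summed symbols 816, voom 754 and leaving out the jumping genes 887. The share of higher genes ranged from 36.5% to 48.3% over these. Of the 20 genes with the largest changes 14 passed in each alternative that tested them, and 6 lost their call without paternal saline replicate 1. The fold change of mt-Co1 reversed to 0.19 with quantile normalization, and the cause was not tested.

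With the replicate number as a block 383 genes passed, 185 higher and 198 lower, 340 of them among the 814, and 4 lists passed in limma's camera that had not: collagens (adjusted p = 0.0291), TGF-beta (0.0402), fatty acid synthesis (0.0497), and Kupffer cells and macrophages (0.00952). Over all tested genes, deviations of same-numbered libraries correlated at 0.007, 0.056 and 0.049, and the block costs degrees of freedom. Some marker sums still followed the number. In order of replicate, Kupffer cell and macrophage genes summed to 474, 537 and 932 RPKM in paternal saline and 466, 843 and 1506 in paternal nicotine. Blood genes summed to 1001, 461 and 1281 against 1011, 421 and 1106 RPKM. Hepatocyte genes ran in opposite orders in the groups. Whether the numbers mark a shared condition was not tested.

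With an estimated correlation 0 of 27 pathway lists and 0 of 15 cell type lists passed in camera, with lowest adjusted p of 0.169 and 0.502, against 14 and 3 with the preset one; the fibrosis matrix list moved to 0.44. Of the 14 lists, 10 passed in fry as well, and fry's mixed test gave 7 cell type lists. The cell type count was 1 without the jumping genes and ranged from 1 without paternal nicotine replicate 2 to 5 without replicate 1. In both settings with 1 the neutrophil and acinar lists had fewer than 5 tested members and were not tested, so these are not lost calls. The collagen list ranged from 0.00154 without paternal saline replicate 3 to 0.292 without paternal nicotine replicate 3, and TGF-beta was at 0.0434 among genes with a mean of at least 5 RPKM; the causes were not tested. The mean correlation of replicates, 0.9557, was 0.9773 without a filter, 0.9278 at a mean of at least 5 RPKM, 0.9328 and 0.9105 with pseudocounts of 0.1 and 0.01, 0.915 with voom and 0.9763 without the jumping genes. Apart from voom on the recovered reads, count-based alternatives (another count test, other size factors, a normalized unit in place of counts) were not run.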

Other observations

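The tests chosen after the result was seen are those of gene families grouped by symbol, of few genes taking most of the reads, of neutrophil RNA, of shared conditions, of the splits for single genes, of pancreatic tissue, of a change with the fathers' nicotine, and of few reads behind each value. Grouped by the letters of their symbols, 229 families were tested with camera. Of 23 tested Sec genes, several of which encode parts of the translocation channel and of transport vesicles of the secretory pathway, 6 rose and 17 did not pass (adjusted p = 0.000195), among them Sec61a1, from 12.8 ± 1.97 to 25.8 ± 2.05 RPKM (SD, n = 3 per group), and Sec61b, from 34.5 ± 6.47 to 67.8 ± 2.96 RPKM. Of 8 Tmed genes, which encode cargo receptors of transport vesicles, 4 rose (adjusted p = 0.0159), and Tmed3 rose from 6.28 ± 0.134 to 15.6 ± 1.06 RPKM. Both families had adjusted p = 0.978 with an estimated correlation.

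Among families of metabolic enzymes 15 of 52 Cyp genes fell and 2 rose (camera adjusted p = 0.00022), 6 of 11 carboxylesterase genes fell (0.000118), 7 of 12 Hsd genes fell (0.000118), 6 of 16 Ugt genes fell (0.000496), 7 of 12 Akr genes fell (0.000538) and 4 of 5 Car genes fell (0.00022). Hsd3b3 fell from 5.61 ± 1.27 to 0.763 ± 0.414 RPKM and Car14 from 11.7 ± 1.29 to 1.95 ± 0.238 RPKM. Each of these families had adjusted p = 0.978 with an estimated correlation, and each kept its direction and passed with median-ratio scaling, while quantile normalization was not run on families. Many of the genes are also in the fixed lists.

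Of the 10 splits of the 6 libraries into groups of 3, 1 gave as many as 814 genes, the real one, and the highest other gave 3. For pathway lists 4 splits gave as many as the 14 of the real one, with a highest other of 14. For cell type lists all 10 splits gave as many as the 3 of the real one, with a highest other of 10 in the split that joins paternal saline replicates 1 and 3 with paternal nicotine replicate 1. This may point to a structure of the samples or to correlated list members, and was not tested further. With 10 splits the share is never under 0.05.

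Of 30 tested acute phase genes 19 rose and 2 fell in the paternal nicotine livers. A few genes taking most of the reads would predict a shift that rescaling removes, and the median log2 fold change of the list was 1.85 after median-ratio scaling, which argues against it. For RNA of neutrophils, 16 of the 19 members that rose gained more RPKM than S100a8 and S100a9 together. These are the most abundant neutrophil transcripts and gained 41.6 RPKM. Levels may not compare between genes, and S100a9 was at 1.64, 35.2 and 7.69 RPKM in the paternal nicotine libraries. The comparison therefore cannot decide how much neutrophil RNA contributed. A condition shared by all animals of a group, such as a father, a litter or a day of dissection, cannot be told apart from the fathers' treatment, because 0 kinds of label split a group by it. Such a shared condition, a contribution of neutrophil RNA and a biological difference that goes with the fathers' nicotine all stay open.

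Pancreatic acinar genes were high in paternal nicotine replicate 2 alone, with Ctrb1 at 1621, Prss2 at 662 and Cela2a at 471 RPKM. Against 3 reads per library in the libraries at 0, Ctrb1 was at least 29300-fold higher. Reads shared between paralogs are argued against, since 12 of 12 members without a near-identical copy were at least 10 times higher in that library. That 0 of 19 members were higher in replicates 1 and 3 than in each paternal saline library restates that they are high in replicate 2 alone, so a change that goes with the fathers' nicotine stays open for that animal. Pancreatic tissue in that library is a candidate source, with 17 of 19 members at least 10 times higher there than in any other library.

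In 126 genes the values jump between near 0 and high within a group, 66 of them within paternal saline and 86 within paternal nicotine. The 89 that are not high in paternal nicotine replicate 2 alone had a median of 2253 reads in their highest library, but their selection at 5 RPKM or more already implies a median of 683.6, so this decides nothing about few reads. Reads shared between overlapping genes or near-identical copies may contribute: 74.2% of the 89 genes have such a partner against 45.8% of 445 other genes matched on mean RPKM, a difference of 28.4 percentage points (Fisher's exact test, two-sided, p = 8.41e-07). Fisher's test treats genes as independent, but several of the 89, such as the Mup genes, are near-identical copies of each other. That p-value may therefore be too small. Of the 126 genes 3 passed the threshold: Saa2, Mup17 and S100a13. No biological explanation was tested for this pattern.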
